A study of Mus musculus with 6 samples.

How the data were processed

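The series holds 6 RNA-seq libraries of MIN6 cells, 3 transfected with PTHrP and 3 with the DsRed vector. The values used are raw counts per gene and library in a table the authors deposited. Per the submitters' processing notes, the reads were handled with bcl2fastq, STAR and the Subread program featureCounts 2.0.3 on the mouse build GRCm38. The annotation, the strand setting and the rule for reads that match several places are not given in the sources used here, so counts of overlapping genes, opposite-strand neighbours and near-identical copies are uncertain. Groups and replicate numbers were taken from the library titles. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

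The table had 55774 entries, of which 287 repeated 168 Ensembl identifiers with identical counts. The repeats were removed, which left 55487 genes. Library totals were 86806601, 84427033 and 94613684 counts for PTHrP and 86686554, 88595892 and 91010177 counts for DsRed. No pair of libraries agreed within sampling noise, as the chi-square per gene was 8.96 to 69.8 over all pairs, so each was kept as its own replicate.

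Genes were filtered with filterByExpr by group, which kept 21141, and scaled with TMM factors. The test was the edgeR 4.0.16 quasi-likelihood F-test with robust dispersions and a group term alone (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 17.7%. Fold changes are PTHrP minus DsRed on the log2 scale, and the SE is the coefficient divided by the square root of its F value, an approximation. CPM values are TMM-scaled. Percentages given for Ins2 are unscaled shares of the library's own counts, while CPM of single genes per library are TMM-scaled too.

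The 28 gene lists were written before the data were examined. Each was tested with camera (limma 3.58.1) on voom log2 CPM with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 28 lists. The same test with a correlation estimated for each list, and the rotation test fry, were run as alternatives. Means and medians of a list are from the voom fit, and values of its members are from the edgeR fit. A list was tested when at least 5 of its members were measured. Member counts are given over all genes tested and adjusted over the list alone. For the per-library means of 4 lists, an exact permutation test over the ways to divide the 6 libraries was used, and its smallest two-sided p is 0.1. Their 95% intervals rest on the spread between the 3 libraries of each group. Log2 CPM values for these means carry a prior count of 2.

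The named genes follow a rule written before the data were examined. It takes Pthlh and Pth1r, 12 fixed genes of ER stress and the beta cell, and the genes past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap, up to 12 in each direction. It adds the 5 with the smallest p in a direction with fewer than 5 such genes, and up to 4 members with the smallest p of each list, given as values where they did not pass. Genes of PTHrP replicate 2 in the last paragraph of the results, Ewsr1, Psat1, Aldh18a1, Gdf15, Eif2ak3, Sec24d, Sec61a1, Ttr, Dnajb11, Dnajc3, Hsp90b1, Hk2 and Aldh1a3, and the overlap partner genes were chosen after their values were seen.

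Alternatives written before the data were examined were RLE and upper-quartile factors, library sizes alone, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a term, a gene length correction, a minimum fold change of 1.2, Pthlh left out of the library sizes, and each library left out in turn. Library quality weights, a GC correction and length and GC corrections together were added after the data were seen, as were list means over only the entries measured in all 6 libraries for lists whose entries changed when a library was left out. Gene positions, exon lengths and GC contents were taken from GENCODE M21 on GRCm38, and 99.9% of the tested genes had a length and a GC content. Each trend was removed per library with a lowess curve through offsets.

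The scripts were tested on simulated counts drawn from the means of these 6 libraries, with 50 genes changed at each fold size. In 20079 genes the edgeR step recovered 22% of the genes changed 1.25-fold, 66% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 1 unchanged gene was called. In 21141 simulated genes DESeq2 recovered 28%, 72%, 90% and 100% at these sizes, and 20 unchanged genes made up 12.1% of its calls. A change under 1.5-fold in a single gene can therefore be missed with 3 libraries per group. The simulated counts held no divergent library, genes were drawn independently, and only genes above 1 CPM were changed. The recovered shares may therefore be lower in the real libraries.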

Results

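RNA was sequenced from MIN6 cells, a mouse insulin-secreting line used as a model of the pancreatic beta cell. The cells had been transiently transfected with either full-length parathyroid hormone-related protein (PTHrP, encoded by Pthlh) or the control vector for the red fluorescent protein DsRed. RNA was taken at most 3 days after transfection, and there were 3 libraries in each of the 2 groups. The libraries held 84427033 to 94613684 gene counts each, and 21141 genes had enough counts to be tested. The series title puts the question to be answered as the effect of PTHrP on stress of the endoplasmic reticulum (ER). No untransfected library was analysed here, so every difference below is PTHrP against DsRed and not against resting cells. Levels are TMM-scaled CPM, the share of a library's counts, as mean ± SD with n = 3, and fold changes are on the log2 scale with an approximate standard error (SE).

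Pthlh itself separated the groups in every library. It had 697, 553 and 797 counts in the PTHrP libraries and 0, 4 and 8 counts in the DsRed libraries, or 7.66 ± 1.01 CPM against 0.0444 ± 0.0437 CPM. The log2 fold change was 7.36 with an SE of 0.40 (edgeR quasi-likelihood test, adjusted p = 4.09e-05). The ratio of library-scaled summed counts was 171, with a 95% interval of 97.6 to 331 that covers counting error only. The mean level of Pthlh in the PTHrP libraries lay at the 55.3 percentile of the genes tested, a level that counts only the part of the construct matching the mouse gene. Pth1r, the receptor for PTHrP, was at a low level in both groups, 0.152 ± 0.0426 CPM with PTHrP and 0.258 ± 0.101 CPM with DsRed, and did not pass the test (adjusted p = 0.771).

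Few genes passed the test between the groups, and most of those that did are genes of ER stress and ER protein folding. Beyond Pthlh, 3 genes rose and 5 fell in the PTHrP group, and each of the 5 that fell belongs to the ER folding and ER stress lists. Hspa5, the major ER chaperone BiP, fell from 2418 ± 204 CPM in DsRed to 1647 ± 55 CPM in PTHrP, a log2 fold change of -0.55 (SE 0.06, adjusted p = 0.0121). Xbp1, the transcription factor activated by the ER stress sensor IRE1, fell by 0.41 on the log2 scale (SE 0.05, adjusted p = 0.0140), and Dnajb9, an ER co-chaperone of BiP, by a log2 fold change of -0.55 (SE 0.06, adjusted p = 0.00645). Manf, a secreted ER stress protein, had a log2 fold change of -0.60 (SE 0.07, adjusted p = 0.0138), and Hspa13, an Hsp70 family member of microsomes, one of -0.49 (SE 0.07, adjusted p = 0.0398).

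The genes that rose were Pck2, Rhbdd3 and Mettl27. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, rose from 126 ± 1.80 CPM to 195 ± 2.64 CPM, a log2 fold change of 0.63 (SE 0.05, adjusted p = 0.000830). Rhbdd3, a rhomboid domain protein, rose by 0.65 (SE 0.08, adjusted p = 0.0140), from 30.1 ± 2.63 CPM to 47.2 ± 1.38 CPM. Mettl27, a putative methyltransferase, rose by 0.85 (SE 0.11, adjusted p = 0.0140), from 11.3 ± 1.29 CPM to 20.4 ± 1.2 CPM. Exons of Rhbdd3 overlap those of Ewsr1 on the opposite strand over 258 bases, and reads there cannot be assigned without strand. Ewsr1 had 602 CPM in PTHrP and 579 CPM in DsRed. Exons of Manf overlap on the opposite strand those of Dcaf1 over 146 bases (137 CPM in PTHrP and 145 CPM in DsRed) and of 4930524O07Rik over 166 bases (0.296 CPM and 0.483 CPM), and on the same strand those of Rbm15b over 14 bases (131 CPM and 134 CPM). Exons of Pck2 overlap those of Gm10876 over 53 bases and exons of Dnajb9 those of Mir5627 over 14, both on the opposite strand, and neither partner was among the genes tested. In each of the 9 genes all 3 PTHrP libraries lay on one side of all 3 DsRed libraries.

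**Figure D1:**
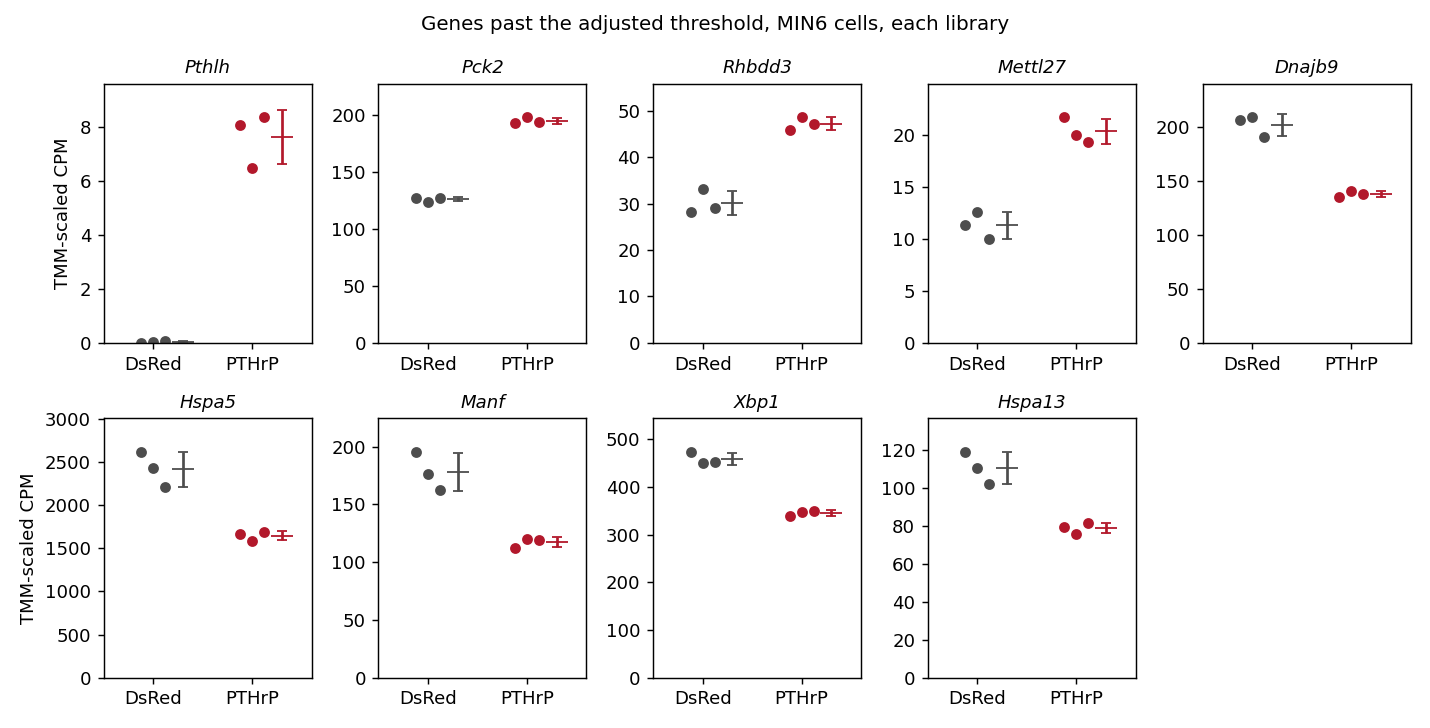
Each dot is the level of one gene in one library (vertical axis, TMM-scaled CPM from 0; horizontal axis, group), with the group mean and SD (n = 3) drawn beside the dots. Pthlh, Pck2, Rhbdd3 and Mettl27 were higher in all 3 PTHrP libraries, and Dnajb9, Hspa5, Manf, Xbp1 and Hspa13 were lower in all 3.

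The next genes with higher levels in PTHrP missed the threshold. Amdhd2, an enzyme of amino sugar metabolism, had a log2 fold change of 0.52 (adjusted p = 0.0539). Shmt2, the mitochondrial serine hydroxymethyltransferase, had 0.44 (adjusted p = 0.0638), and Mars1, the methionyl-tRNA synthetase, 0.37 (adjusted p = 0.0711). Kcnj11, the pore subunit of the beta cell ATP-sensitive potassium channel, had 0.46 (adjusted p = 0.0711), and the linker histone H1f0 had 0.33 (adjusted p = 0.0834). Exons of Mars1 and Ddit3 overlap on opposite strands over 68 bases, those of H1f0 and Gm49544 over 163 and those of Shmt2 and Ndufa4l2 over 32.

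In total 9 of 21141 genes passed (4 higher, 5 lower), and 1881 had an unadjusted p under 0.05 (1040 higher, 841 lower). The groups did not overlap for 16.3% of the genes tested. An average over all splits of the libraries gives 10% for genes without ties, and a single split can lie far from it. The share in the other splits was not computed, so 16.3% is not read as an excess. In positions of the mouse build GRCm38, Pthlh lies on chromosome 6 at 147252101 to 147264183, Hspa5 on chromosome 2 at 34771970 to 34777547, and Xbp1 on chromosome 11 at 5520659 to 5525893. Dnajb9 is on chromosome 12 at 44205559 to 44210326, Manf on chromosome 9 at 106838312 to 106891979, and Hspa13 on chromosome 16 at 75745431 to 75767104. Pck2 is on chromosome 14 at 55540266 to 55551242, Rhbdd3 on chromosome 11 at 5098926 to 5106093, and Mettl27 on chromosome 5 at 134932368 to 134942637. All 9 are annotated as protein-coding genes.

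The number of calls rested on single libraries. It was 4 without PTHrP replicate 1, 213 without PTHrP replicate 2, 14 without PTHrP replicate 3, 4 without DsRed replicate 1, 2 without DsRed replicate 2 and 17 without DsRed replicate 3, and no lower gene passed without DsRed replicate 1 or without DsRed replicate 2. Pthlh and Pck2 passed in all 6 of these fits. The log2 fold change of Hspa5 ranged from -0.62 to -0.50 over them (adjusted p from 0.000336 to 0.119), that of Xbp1 from -0.42 to -0.39 (0.000365 to 0.150), that of Dnajb9 from -0.59 to -0.52 (8.21e-05 to 0.0963), that of Manf from -0.66 to -0.53 (0.000324 to 0.119) and that of Hspa13 from -0.54 to -0.44 (0.00164 to 0.389). Manf, Xbp1 and Hspa13 also missed the threshold without PTHrP replicate 1 and without PTHrP replicate 3. Rhbdd3 (0.60 to 0.72, adjusted p from 0.000581 to 0.0974) and Mettl27 (0.77 to 0.93, 0.000654 to 0.0974) passed in the fit without PTHrP replicate 2 and in none of the other 5. Whether the replicate numbers pair the samples is not known. With the number as a block 7 genes passed, 4 of them among the 9, and Xbp1, Manf, Hspa13, Rhbdd3 and Mettl27 missed the threshold.

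Other commonly used markers of ER stress did not pass. Ddit3 (CHOP), a transcription factor of stress-induced apoptosis, had 116 ± 9.38 CPM in PTHrP and 117 ± 3.27 CPM in DsRed, a log2 fold change of -0.02 (SE 0.07, adjusted p = 0.952). Atf4, the transcription factor downstream of the sensor PERK, had a log2 fold change of 0.05 (adjusted p = 0.872), and Trib3, an Atf4 and CHOP target, 0.10 (adjusted p = 0.624). Herpud1, an ER-associated degradation component, had -0.08 (adjusted p = 0.780). Txnip, a thioredoxin inhibitor linked to beta cell stress, had 0.15 with an SE of 0.46 (adjusted p = 0.951), which moved between -0.21 without DsRed replicate 3 and 0.37 without DsRed replicate 1.

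Gene lists fixed before the data were examined placed the ER folding and degradation genes lower in PTHrP. Of 24 ER chaperones and folding enzymes, 23 had negative fold changes, with a mean of -0.23 and a median of -0.19. Over all genes 3 of them fell (Hspa5, Manf and Hspa13), and 9 passed, all lower, when adjusted over the list alone. Beside those 3, Creld2, a stress-inducible ER protein, had -0.43, Dnajb11, a BiP co-chaperone, -0.33, Dnajc3, an ER co-chaperone that also inhibits PERK, -0.39, and Hsp90b1, the ER Hsp90 GRP94, -0.25. The list was lower than other genes with the preset correlation (camera, adjusted p = 8.66e-15), and the adjusted p was 0.354 with an estimated correlation.

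Targets of IRE1 and XBP1, genes of ER-associated degradation (ERAD) and of ER translocation went the same way. Of 31 members 29 had negative fold changes, with a mean of -0.20 and a median of -0.22. Over all genes 2 fell (Dnajb9 and Xbp1), and 16 passed, all lower, when adjusted over the list alone. Ssr3, a subunit of the translocon-associated complex, had -0.34, Spcs2, of the signal peptidase complex, -0.26, Sec24d, a coat protein of ER export vesicles, -0.62, and Sec61a1, the translocation channel, -0.32. With camera the adjusted p was 2.42e-15, and the adjusted p was 0.222 with an estimated correlation.

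Targets of PERK and ATF4 lay on the other side. Of 32 members 22 had positive fold changes, with a mean of 0.14 and a median of 0.11. No member passed over all genes, though the fixed list does not hold Pck2, which did. When adjusted over the list alone 8 members passed, 7 higher and 1 lower. Those higher were enzymes of serine, one-carbon and amino acid synthesis, Shmt2 (0.44), Mthfd2 (0.27), Asns (0.24), Aldh18a1 (0.34) and Psat1 (0.22), together with the translation repressor Eif4ebp1 (0.53) and the stress cytokine Gdf15 (1.83, at 0.416 CPM in PTHrP and 0.116 CPM in DsRed). The lower one was Eif2ak3, which encodes PERK itself (-0.20). The stress transcription factors of the list, Atf4 and Ddit3, were not among them. The camera adjusted p was 6.33e-05, and the adjusted p was 0.248 with an estimated correlation. Without DsRed replicate 1 the mean was 0.09 (camera adjusted p = 0.000914).

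The 18 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include many ATF4 targets, also had higher levels in PTHrP. Positive fold changes were seen for 15 of them, with a mean and median of 0.13. None passed over all genes, and 8 passed, all higher, when adjusted over the list alone, among them Mars1 (0.37), Lars (0.27), Gars (0.23) and Yars (0.21). With camera the adjusted p was 2.52e-07, and the adjusted p was 0.222 with an estimated correlation.

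**Figure D2:**
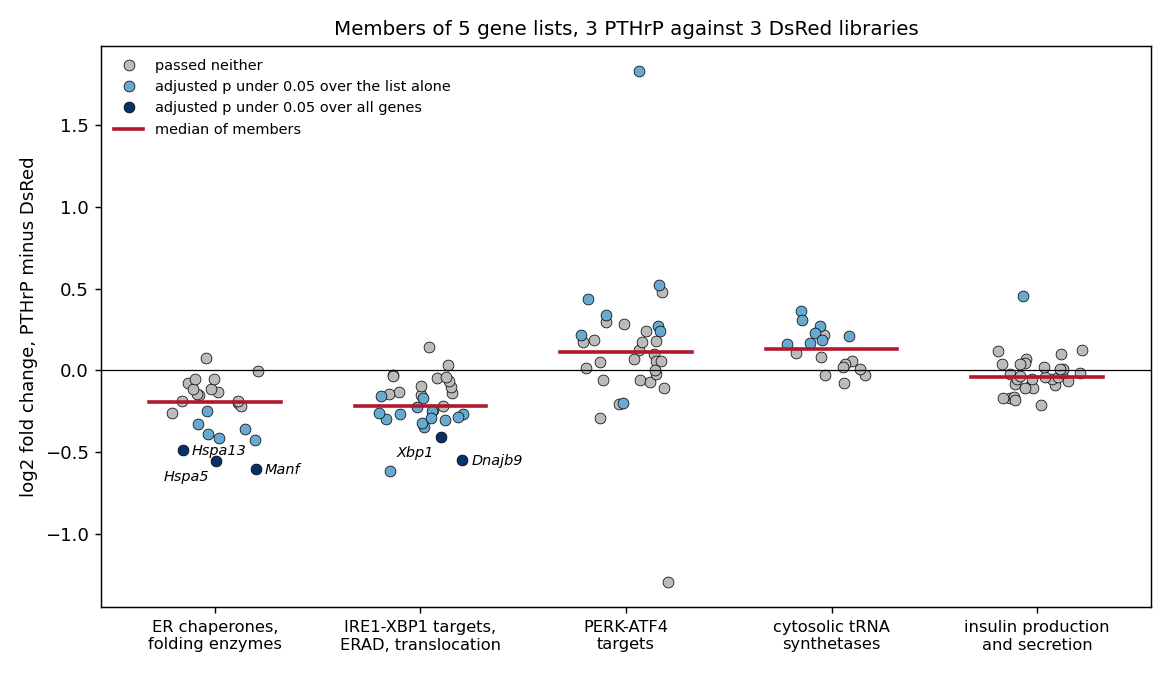
Each dot is the log2 fold change of one gene between 3 PTHrP and 3 DsRed libraries (vertical axis), by gene list (horizontal axis), and red lines are medians of the members drawn. Dark dots passed over all genes and light blue dots only when adjusted over the list alone; 23 of 24 chaperones lay below 0, and 15 of 18 tRNA synthetases lay above it.

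Taken per library, the mean log2 CPM of the 55 folding and ERAD genes was 7.31, 7.24 and 7.32 in PTHrP and 7.60, 7.51 and 7.42 in DsRed. The difference was -0.22, with a 95% interval of -0.38 to -0.06 from the spread between libraries (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 can give). For the ATF4 list the difference was 0.14, with an interval of -0.03 to 0.30 that includes 0. The mean log2 CPM of that list was 6.10, 6.07 and 6.12 in PTHrP and 5.86, 5.96 and 6.05 in DsRed. DsRed replicate 3 thus lay close to PTHrP replicate 2. For the tRNA synthetases the difference was 0.13 with an interval of 0.05 to 0.20. The exact permutation p was 0.1 for each.

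**Figure D3:**
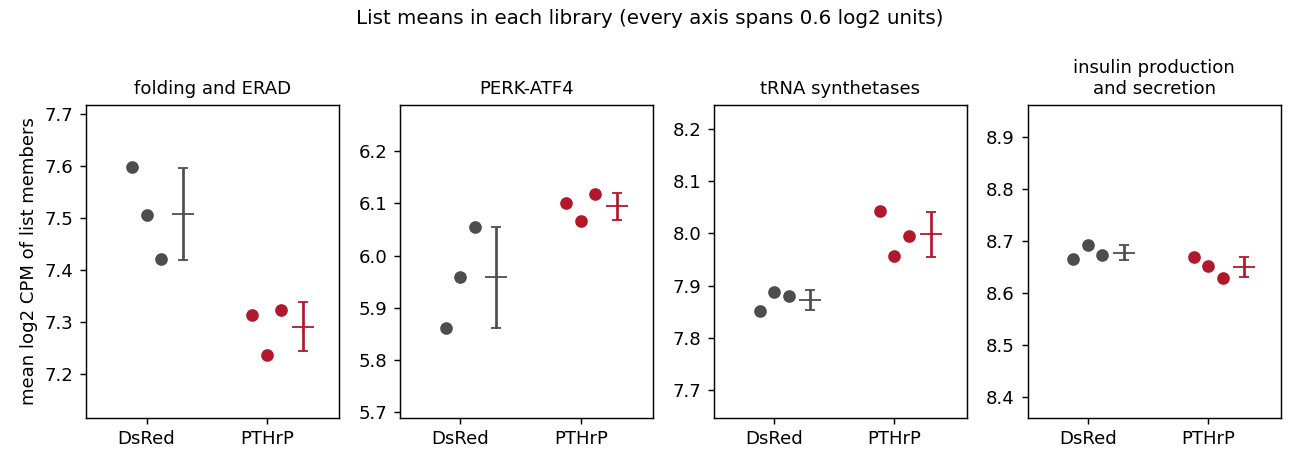
Each dot is the mean log2 CPM of a gene list (vertical axis, 0.6 units in every panel, not starting at 0) in one library, by group (horizontal axis), with the group mean and SD (n = 3) beside the dots. The 3 PTHrP libraries lay below the DsRed libraries for folding and ERAD genes and above them for the ATF4 and tRNA synthetase lists, and the groups overlapped for the insulin list.

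Beta cell identity and insulin genes did not pass over all genes. Ins1 and Ins2, the mouse insulin genes, are near-identical copies whose reads could be split in counting, and they had log2 fold changes of -0.05 (adjusted p = 0.916) and -0.06 (adjusted p = 0.905), and Ins2 alone took 3.30% to 4.29% of the counts of a library. Pdx1 (-0.08, adjusted p = 0.672), Mafa (-0.27, SE 0.22, adjusted p = 0.787) and the glucose transporter gene Slc2a2 (-0.07, adjusted p = 0.859) did not pass either. Mafa had 804 CPM in PTHrP replicate 2, 1407 and 1319 CPM in the other PTHrP libraries and 1389 to 1450 CPM in DsRed, and its fold change was -0.06 without PTHrP replicate 2 and -0.42 without PTHrP replicate 1. In the list of 31 insulin production and secretion genes, Kcnj11 was the only one that passed, higher, when adjusted over the list alone, and none passed over all genes. The mean of that list was -0.03 (camera adjusted p = 0.317), and its next members were the prohormone convertase Pcsk1 (-0.21) and the exocytosis protein Snap25 (-0.17). Of 17 beta cell transcription factors none passed over all genes and 2 passed, both lower, when adjusted over the list alone, St18 (-0.35) and Neurod1 (-0.22), with a list mean of -0.08 (camera adjusted p = 0.129). That list passed camera without PTHrP replicate 1 (-0.15, adjusted p = 0.00495) and without DsRed replicate 3 (-0.12, adjusted p = 0.0166), while its mean was -0.03 without PTHrP replicate 2 (adjusted p = 0.613) and -0.05 without DsRed replicate 1 (adjusted p = 0.693). With all 6 libraries its adjusted p was 0.683 with an estimated correlation. The 11 measured disallowed and dedifferentiation genes, which beta cells normally keep low, had a mean of -0.15 (camera adjusted p = 0.317). Acot7 was at -0.39 and Ldha at 0.23, and none passed by either adjustment. Leaving out 1 library moved Acot7 between -0.54 and -0.27 and Ldha between 0.09 and 0.37. The list mean moved between -0.34 without DsRed replicate 1 and -0.07 without PTHrP replicate 3, in fits that also measured Aldh1a3. Over the 11 alone it was -0.22 and -0.10 there, and -0.28 without PTHrP replicate 2. It was -0.07 without PTHrP replicate 1 and -0.09 without DsRed replicate 2 over the same 11.

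Genes that respond to cAMP, the messenger of the PTHrP receptor, mostly had negative fold changes. Of 23 genes in this list, which also holds Pth1r, 21 had negative fold changes, with a mean of -0.24. None passed over all genes, and 2 passed, both lower, when adjusted over the list alone, the cAMP-responsive repressor Crem (-0.30) and the early response gene Fosb (-0.91), while Klf4 had -0.39 and Nr4a2 -0.42. The camera adjusted p was 3.14e-06, and the adjusted p was 0.462 with an estimated correlation. DsRed replicate 3 lay with the PTHrP libraries: the mean log2 CPM of the list was 5.6, 5.58 and 5.52 in PTHrP and 5.92, 5.92 and 5.57 in DsRed, and Klf4 and Nr4a2 had 37.0 and 247 CPM in that library against 36.6 and 242 CPM in the PTHrP mean. Without it the mean fold change of the list was -0.36, against -0.19 without DsRed replicate 1 and -0.18 without DsRed replicate 2. Of 14 cytosolic heat shock genes 12 had negative fold changes, with a mean of -0.14. None passed over all genes, and Hsph1 (-0.41), Dnaja1 (-0.22) and Bag3 (-0.60) passed when adjusted over the list alone. In camera the adjusted p was 0.00262, and the adjusted p was 0.222 with an estimated correlation.

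In the metabolic, sterol and ribosomal lists no member passed by either adjustment. Of 19 measured glycolysis and hypoxia genes 18 had positive fold changes, with a mean of 0.18, including the oxygen sensor Egln1 (0.78) and the glycolytic enzymes Pgk1 (0.25), Tpi1 (0.19) and Gapdh (0.25). The list test held 20 entries, as Aldoa has 2 gene identifiers in the table. The camera adjusted p was 4.01e-06, and the adjusted p was 0.523 with an estimated correlation. In the fits without PTHrP replicate 1, 2 or 3 or DsRed replicate 1, Hk2, a hexokinase gene, also passed the count filter, with a log2 fold change of -2.70, -1.78, -1.66 and -2.77 in turn. The mean over these 21 entries was 0.05, 0.11, 0.06 and 0.06, and over the 20 entries measured in all 6 libraries, a set taken after the data were seen, it was 0.19, 0.20, 0.15 and 0.20. Without DsRed replicate 3 the mean of the 20 entries was 0.09 (camera adjusted p = 0.0236), and Pgk1, Tpi1 and Gapdh had 0.16, 0.10 and 0.15.

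Of 26 nuclear-encoded oxidative phosphorylation subunits 22 had positive fold changes, with a mean of 0.06, such as Cyc1 (0.13) and Atp5a1 (0.13). In camera the adjusted p was 0.000764, and the adjusted p was 0.576 with an estimated correlation. The mean was 0.02 without PTHrP replicate 2, where the list did not pass (adjusted p = 0.0949), 0.04 without DsRed replicate 1, 0.10 without PTHrP replicate 1 and 0.11 without DsRed replicate 3. All 11 measured mRNAs of the mitochondrial genome had negative fold changes, with a mean of -0.21, such as mt-Nd5 (-0.32) and mt-Nd2 (-0.36). Mitochondrial genome entries held only 0.0464% (PTHrP replicate 1) to 0.0736% (DsRed replicate 3) of a library's counts. The values of this list rest on that small share and are not read as a change in mitochondrial transcript content. The camera adjusted p was 0.00375, and the adjusted p was 0.576 with an estimated correlation. That list did not pass without PTHrP replicate 1 (mean -0.04 over 12 measured, adjusted p = 0.255; -0.09 over the 11, adjusted p = 0.183) or without DsRed replicate 3 (mean -0.05, adjusted p = 0.314). Its mean over the 11 was -0.32 without PTHrP replicate 2 and -0.32 without DsRed replicate 1.

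Of 23 sterol synthesis genes 17 had negative fold changes, with a mean of -0.09, including Hmgcs1 (-0.33) and Idi1 (-0.40), whereas Mvk had 0.34. In camera the adjusted p was 0.00737, and the adjusted p was 0.659 with an estimated correlation. Of 49 cytosolic ribosomal protein genes 41 had positive fold changes, with a mean of 0.08, such as Rps2 (0.21). Leaving out 1 library moved Rps2 between 0.09 and 0.28. The camera adjusted p was 0.00217, and the adjusted p was 0.683 with an estimated correlation. Without PTHrP replicate 2 the means of the sterol and ribosomal lists were 0.00 and -0.03, so both directions turned on that library. The sterol list also missed the threshold without DsRed replicate 1 (-0.07, adjusted p = 0.0638) and without DsRed replicate 2 (-0.06, adjusted p = 0.193), and its mean was -0.14 without PTHrP replicate 3 and without DsRed replicate 3. The ribosomal list missed it without DsRed replicate 1 (0.05, adjusted p = 0.0638), and its mean was 0.04 without DsRed replicate 2, 0.17 without PTHrP replicate 1 and 0.16 without DsRed replicate 3. It also lost its call in camera with the gene length correction and with length and GC corrections together, where 10 lists passed.

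Cell death and cell cycle lists did not pass in camera. The rotation test fry, which asks whether a list's own genes change in either direction and does not compare them with other genes, gave an adjusted p of 0.0273 for apoptosis regulators, 0.00534 for S and G2/M phase genes and 5.5e-05 for G1 cyclins, kinases and inhibitors. Of 21 measured apoptosis regulators none passed by either adjustment and the mean was 0.04 (camera adjusted p = 0.895), with the pore-forming Bax at 0.17. That mean was 0.13 without DsRed replicate 1, and below 0 without PTHrP replicate 3 (-0.02) and without DsRed replicate 3 (-0.01). The 18 measured p53 targets had a mean of -0.06 (camera adjusted p = 0.385), with none passing by either adjustment and Tigar at -0.23 (-0.12 without PTHrP replicate 2). The p53 mean was -0.01 without DsRed replicate 1, -0.01 without PTHrP replicate 2, -0.11 without PTHrP replicate 3 and -0.12 without DsRed replicate 3. Among 30 S and G2/M phase genes, Ccne2 (-0.33) passed when adjusted over the list alone and none over all genes, with a mean of -0.01 (camera adjusted p = 0.979; -0.02 without DsRed replicate 3 and 0.00 without PTHrP replicate 2). Among 17 G1 cyclins, kinases and inhibitors, Ccne2 and the inhibitor Cdkn2d (0.23) passed when adjusted over the list alone and none over all genes, with a mean of -0.08 (camera adjusted p = 0.353). Of 9 measured replication-dependent histone genes, H1f2 (0.64) and H1f3 (0.60) passed, both higher, when adjusted over the list alone and none over all genes, with a mean of 0.00 (camera adjusted p = 0.310). The histone mean was 0.19 without PTHrP replicate 2, 0.09 without DsRed replicate 3 and -0.15 without PTHrP replicate 3.

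Immune and stress response lists did not pass camera with all 6 libraries either. The 33 interferon response genes had a mean of -0.09 (camera adjusted p = 0.129), which was -0.01 without PTHrP replicate 1 and -0.15 without PTHrP replicate 2, with Stat2 at -0.24 and Cxcl10 at 0.47. The 12 antigen presentation genes had a mean of -0.07 (camera adjusted p = 0.353), with Psmb10 at -0.27. The antigen presentation list passed without DsRed replicate 3 (-0.12, adjusted p = 0.0438), while its mean was -0.04 without DsRed replicate 1 (adjusted p = 0.760) and -0.04 without PTHrP replicate 1 (adjusted p = 0.623), and with all 6 libraries its adjusted p was 0.745 with an estimated correlation. The 13 measured NF-kB and cytokine genes had a mean of -0.12 (camera adjusted p = 0.943), with Relb at 0.16, and the mean was -0.03 without PTHrP replicate 2, -0.04 without DsRed replicate 1, -0.18 without DsRed replicate 2 and -0.23 without PTHrP replicate 3. The 19 NRF2 and antioxidant genes had a mean of 0.01 (camera adjusted p = 0.981), with Gclc at -0.15. That mean was below 0 without PTHrP replicate 3 (-0.03), DsRed replicate 1 (-0.03) or DsRed replicate 2 (-0.05), and was 0.10 without DsRed replicate 3. No member of these 4 lists passed by either adjustment. Of 21 autophagy and lysosome genes, the lysosomal channel Mcoln1 (0.26) passed when adjusted over the list alone and none over all genes, with a mean of 0.03 (camera adjusted p = 0.0837). The autophagy list passed camera without PTHrP replicate 1 (0.04, adjusted p = 0.0191) and without DsRed replicate 2 (0.04, adjusted p = 0.0204), while its mean was 0.01 without DsRed replicate 1 (adjusted p = 0.241) and 0.02 without PTHrP replicate 2 (adjusted p = 0.316). Its adjusted p with all 6 libraries was 0.576 with an estimated correlation.

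Markers of other cell types were mostly at low levels in both groups. Gcg, the glucagon gene of alpha cells, had 159 CPM in PTHrP and 148 CPM in DsRed, and Ttr, also abundant in alpha cells, 214 CPM and 222 CPM. The 6 measured alpha, delta and PP cell markers had a mean of 0.28 (camera adjusted p = 0.310). Their mean was 0.44 without PTHrP replicate 2, where the list passed (adjusted p = 0.0191), and 0.15 without PTHrP replicate 1 (adjusted p = 0.623) and without DsRed replicate 2 (adjusted p = 0.605), and with all 6 libraries the adjusted p was 0.683 with an estimated correlation. The 8 measured acinar and duct markers had a mean of -0.40 (camera adjusted p = 0.129), and Bhlha15, a secretory cell transcription factor, passed when adjusted over the list alone, at 4.09 CPM against 7.26 CPM (-0.83). The 13 fibroblast markers had a mean of -0.34 (camera adjusted p = 0.396), with Col3a1 at 0.141 CPM in PTHrP and 0.396 CPM in DsRed, and their mean was -0.04 without PTHrP replicate 1, -0.17 without DsRed replicate 3 and -0.52 without PTHrP replicate 2. The 10 immune and endothelial markers had a mean of -0.59 (camera adjusted p = 0.104), with Ptprc at 0.453 CPM and 0.934 CPM. Their mean was -0.69 without DsRed replicate 2, where the list passed (adjusted p = 0.0458), and -0.31 without PTHrP replicate 1 (adjusted p = 0.313), and with all 6 libraries the adjusted p was 0.462 with an estimated correlation. No member of these 4 lists passed over all genes.

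In all, 11 of the 28 lists passed with the preset correlation (5 higher, 6 lower) and none with an estimated correlation, where the smallest adjusted p was 0.222. The rotation test fry gave 7 lists an unadjusted p under 0.05 for movement in one direction, none after adjustment, and 9 lists an adjusted p under 0.05 for change in either direction. Those 9 were the chaperone (0.0218), IRE1-XBP1 (0.00982), ATF4 (0.0216), tRNA synthetase (0.00982), beta cell transcription factor (0.00285), heat shock (0.00644), apoptosis, S and G2/M, and G1 lists. Mean, median and test differed in sign for the S and G2/M, NF-kB and histone lists.

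PTHrP replicate 2 stood apart from the other 5 libraries. The SD of its log2 difference from its group mates over 6110 abundant genes was 0.241, against at most 0.156 in any other library. Actb, the cytoskeletal actin gene, had 428 CPM in it and 1072 to 1214 CPM in the others, Dpysl2, a neuronal cytoskeleton regulator, 14.1 CPM against 97.8 to 111 CPM, and Lars2, the mitochondrial leucyl-tRNA synthetase, 5373 CPM against 3121 to 3473 CPM. The microRNA entry Mir6236 had 1841 CPM against 670 to 780 CPM, the ribosomal RNA entry CT010467.1 950 CPM against 279 to 311 CPM, and Gm10800 135 CPM against 29.3 to 107 CPM. That log2 difference had a Spearman's rho of -0.385 with exon length across genes, which are not independent replicates. The 9 genes past the threshold in all 6 libraries also passed without it.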

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

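The quality weights, GC, length-with-GC and fixed list entry settings were chosen after the data were seen, and all others before. Pthlh passed in all 21 alternatives, with log2 fold changes of 6.81 to 8.29. The count of 9 genes (4 higher, 5 lower) was 9 with RLE factors (4 higher, 5 lower), 13 with upper-quartile factors (5 and 8), 14 with library sizes alone (7 and 7), 220 with no filter (122 and 98), 104 with DESeq2 (67 and 37) and 18 with limma-voom (8 and 10). It was 13 with the gene length correction (4 and 9), 13 with length and GC corrections (4 and 9), 9 with the GC correction (8 of them shared), 11 with the stricter filter, 9 with Pthlh left out of the library sizes, 254 with quality weights (131 and 123), and 2 against a minimum fold of 1.2 (2 and 0). All 9 genes were among the calls of each of these except the GC correction, without Hspa13 (-0.43, adjusted p = 0.103), and the minimum fold, which kept 2 of them. Leaving out 1 library gave 2 to 213 genes, 2 to 142 higher and 0 to 71 lower. The cause of these differences was not tested. The list means over those 6 fits were 0.09 to 0.19 for ATF4 targets, -0.29 to -0.18 for chaperones and -0.24 to -0.17 for IRE1-XBP1 targets, and 9 to 12 lists passed.

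Same-numbered libraries had deviation correlations of 0.171, -0.0617 and -0.0256, and PTHrP replicate 2 correlated best with DsRed replicate 3 (0.175). Deviations from the mean of 3 libraries depend on each other. PTHrP replicate 2 also dominates those of its group (-0.808 and -0.713 with its mates). These values therefore cannot decide whether the numbers pair the samples. The labels do not say so either, and the main fit has no block. With the replicate number as a block 7 genes passed (5 higher, 2 lower), 4 of them shared with the 9. The other 5 had fold changes of -0.41 (Xbp1, adjusted p = 0.0865), -0.60 (Manf, 0.0667), -0.49 (Hspa13, 0.133), 0.65 (Rhbdd3, 0.0505) and 0.85 (Mettl27, 0.0539) under the block, where the values without it were -0.41, -0.60, -0.49, 0.65 and 0.85; the cause of the lost calls was not tested. With the block and gene length correction 12 genes passed (6 higher, 6 lower).

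With an estimated correlation 0 of 28 lists passed, and with fry 0. The list means stay 0.14 for ATF4 targets (adjusted p = 0.248 and 0.116), -0.23 for chaperones (0.354 and 0.133) and -0.20 for IRE1-XBP1 targets (0.222 and 0.0930), since both change the test and not the value. Reversals were seen for sterol synthesis (0.000329) and ribosomal proteins (-0.0260), both without PTHrP replicate 2; over the 6 fits that leave out 1 library their means ran from -0.144 to 0.000329 and from -0.0260 to 0.168. Among 458 values of the other 25 lists, 407 kept their direction and side of the threshold, or changed sign with no call on either side (21), 31 lost and 18 gained a call. Among 2631 values of 126 named genes, these numbers were 2475 (10 with such a sign change), 40 and 116. Depth was 84427033 to 94613684 counts. With 3 libraries per group at this depth the edgeR step recovered 66% of genes changed 1.5-fold in simulated data, which held no divergent library.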

Other observations

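The tests of the folding, ERAD and ATF4 patterns and of a swapped label were chosen after the results were seen, and those of the splits and of length and GC trends in PTHrP replicate 2 before. Without PTHrP replicate 2, 213 genes passed (142 higher, 71 lower; edgeR quasi-likelihood, adjusted p under 0.05), and the genes named here were chosen after their values were seen. Of 18 tRNA synthetases 6 rose, among them Mars1 (0.41), Iars (0.41), Cars (0.34) and Lars (0.29), and of 32 ATF4 targets 6 rose, among them Aldh18a1 (0.46), Shmt2 (0.41) and Mthfd2 (0.30). Of 24 chaperones 8 fell, and of 31 IRE1-XBP1 targets 5 fell, Dnajb9, Xbp1, Ssr3, Ssr1 and Spcs2.

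In the other lists fixed before the data were examined few members passed in those 5 libraries. Of 17 beta cell transcription factors 2 fell, St18 (-0.36) and Neurod1 (-0.23), and of 31 insulin production and secretion genes 1 rose, Kcnj11 (0.48). Of 14 cytosolic heat shock genes 2 fell, Hsph1 (-0.39) and Dnaja1 (-0.25), and of 21 autophagy and lysosome genes 2 rose, Mcoln1 (0.30) and Gabarapl1 (0.23). Of 17 G1 cyclins, kinases and inhibitors 2 fell, Ccne2 (-0.32) and Cdkn1a (-0.34), of which the S and G2/M list also holds the first and the p53 list the second. Single members passed in the cAMP list (Fosb, -0.70), the sterol list (Mvk, 0.47), the mitochondrial genome list (mt-Nd2, -0.54), the acinar and duct list (Bhlha15, -0.97) and the histone list (H1f2, 0.51).

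Folding and ERAD transcripts were lower in PTHrP, and the mean log2 fold change of the 55 genes was -0.22. In camera with an estimated correlation, neither the chaperone list (adjusted p = 0.354) nor the IRE1-XBP1 list (adjusted p = 0.222) passed. Without the divergent library the mean of the 55 genes was -0.19 and after length and GC corrections -0.21, which argues against either as the whole cause. The 5 lower genes passed in both, but they were picked in these same libraries, so this adds no support. No lower gene passed without DsRed replicate 1 or without DsRed replicate 2. The chaperone and IRE1-XBP1 means were -0.18 and -0.17 without DsRed replicate 1, and -0.23 and -0.20 without DsRed replicate 2. Less secretory cargo at the transcript level stays open, since the insulin list differed by -0.0270 (95% interval -0.0660 to 0.0120) with 11 members higher and 20 lower, and a mean over members that go both ways decides nothing. Lower ER load through PTHrP, or higher load through the DsRed control, may each give this pattern, and no untransfected library is there to separate them. Of the 10 splits of the 6 libraries 1 (the real one) gave as many as 9 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

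The mean of the ATF4 list was positive (0.14, and 0.09 without DsRed replicate 1) where that of the folding genes was negative. Over the alternatives that keep all 6 libraries the ATF4 mean ran from 0.09 to 0.17. It includes Gdf15, a low-count gene whose fold change lies far above the list's median of 0.11. If all arms of the unfolded protein response had decreased together, the ATF4 list would lie at or below 0; it differed by 0.14, with a 95% interval of -0.03 to 0.30, which leaves the question open. The ATF4 list, like the insulin list, holds members that go both ways (22 higher, 10 lower), so its mean cannot decide this. A pooled test of ATF4 targets and tRNA synthetases, added only after the ATF4 result, gave 0.13 (interval 0.01 to 0.25). The pooled members also go both ways, and synthetases also respond to other signals, so no conclusion is drawn from it. The real split gave 11 lists past the threshold in camera with the preset correlation, and none passed with an estimated correlation. The other splits, which mix the groups, gave 0 to 10 lists, so camera at the preset correlation also called lists without the real grouping. Estimated correlations were 0.495 for chaperones, 0.197 for IRE1-XBP1 targets and 0.0499 for ATF4 targets, against the preset 0.01. For cytosolic heat shock genes the estimate was -0.0114, below the preset, and the camera adjusted p still went from 0.00262 to 0.222. A larger correlation alone therefore does not account for every lost call. A list that misses with an estimated correlation is not read as unchanged. With 1 of 10 splits reaching 11, the splits are too few for a share under 0.05.

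PTHrP replicate 2 differed from the other libraries. A label swapped with a DsRed library is argued against by its Pthlh level of 6.50 CPM, where DsRed libraries reached at most 0.0874 CPM. Its log2 difference from its mates had a Spearman's rho of -0.385 with exon length across 6110 genes, and against the DsRed mean rho was -0.401 in it, -0.162 in PTHrP replicate 3 and 0.0958 in PTHrP replicate 1, so loss of long transcripts is a candidate explanation for part of the divergence; genes are not independent replicates, and a weaker trend of that sign was also present in PTHrP replicate 3. After length and GC trends were removed its SD was 0.219 (from 0.241), against 0.135 at most elsewhere, so these trends are not the whole cause. Low Dpysl2 (14.1 CPM against 102 in its mates), Gigyf1 (19.9 against 71.8) and Trio (15.7 against 43.9), and high CT010467.1, an rRNA entry (950 against 286), Gm10800 (135 against 39.3) and Cbx3 (68.7 against 27.1), leave open a difference in RNA or library quality or in the cells of that culture.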
